A study of Mus musculus with 6 samples.

How the data were processed

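RNA sequencing had been done on 6 samples of the mouse melanoma line B16.F10, 3 left untreated and 3 given 3.5 µM simvastatin for 24 h, with stranded libraries made from total RNA per the labels' protocols. Samples were grouped by their titles. Reads had been aligned with HISAT2 2.0.5 and processed with StringTie on GRCm38 (mm10), per the submitters' processing notes. The steps between alignment and the deposited tables, the counting, the filter on low values and the test, are not given in the sources used here.

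The main deposited table holds, per the file headers, 1 value for the simvastatin group and 1 for the control group for each transcript, a signed linear fold ratio, a p-value, an adjusted p-value and a yes or no call, all made by the authors. The unit of the group values is not given in the sources used here, and no per-sample value was used. Of the 15905 transcripts, 11645 carried Ensembl identifiers, 4259 were models assembled from reads and 1 had a blank identifier. GENCODE mouse release 21 (GRCm38) held 11635 of the Ensembl transcripts and 8436 of the 8513 gene identifiers, and gave gene types and coordinates. A group was listed at 0 for 103 transcripts, and folds against it are not reported. The p-value was printed as 0 for 184 transcripts. The deposited fold differed from the ratio of the group values by at most 1.22% where both values were at least 1, and 1 fold, of Creb3l2, was not a number and was replaced by that ratio. A Benjamini-Hochberg adjustment of the deposited p-values was recomputed here. Where the printed p-value was over 0.001, it differed from the authors' adjusted p-value by at most 0.0172. Transcripts with a printed p-value of 0.001 or less, which hold the smallest adjusted p-values, were left out of this check. The authors' calls had an adjusted p-value of up to 0.2 and, where the fold was a number, a fold of at least 1.5, and 13 transcripts within these limits had no call. The deposited expression values summed to 344210 and 394749 in the groups, while the median log2 fold change over all transcripts, computed here from the authors' folds, was 0.0144.

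The other deposited tables hold the authors' enrichment terms with gene counts, fold enrichment and adjusted p-values, per the file headers from DAVID. The interaction scores are, per the file headers, those of STRING, from which the authors kept links with a score over 0.7 before deposition. Others hold a table of transcripts linked to aggressiveness, and a comparison with A375 cells. In that comparison the deposited log2 fold change is per gene for the mouse cells, and the z-score, per the file headers, is that of A375 cells given 10 µM simvastatin in an outside signature. A further supplementary table of the series was not analysed here.

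Because only the authors' comparison was given, no test was refitted, and the rule fixed for this case was followed: counts used the authors' adjusted p-value under 0.05, as printed to 3 decimals. It was printed as 0.05 for 38 transcripts, which were not counted. The A375 comparison gives more digits for 6 of these. It holds only entries under 0.05, so these 6 do not show on which side the others lie. With 3 biological replicates per group, as the series text calls them, these p-values measure the spread between cultures only as far as that description holds. No SD, leave-out or block could be computed, and the precision and depth of single values are unknown.

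The 37 gene lists, the thresholds and the rule for naming genes were fixed before the data were examined. The lists' 861 genes were matched to the table by its symbols (572), by GENCODE symbols (3) or by older symbols (5), and 281 were not found. Each gene was represented by its transcript of highest mean value over the groups. Lists with at least 5 measured genes were tested with limma's cameraPR (limma 3.58.1, R 4.3.3) on the sign of the log2 fold change times -log10 of the p-value, with p printed as 0 set to 0.0005 and a preset inter-gene correlation of 0.01. Values were adjusted by the Benjamini-Hochberg method over the 34 lists tested. The list test was tested on simulated data made by shuffling the statistic of the simvastatin comparison over its 8513 genes 100 times and shifting 6 lists by 1. It recovered 57.3% of the shifted lists, called 0% in the wrong direction, and called any list in 6% of shuffles without a shift. Shuffling removes any correlation between genes, so these rates do not show the error rate for lists whose members move together. Members of a list were also adjusted over the list alone.

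Genes were named by that rule: 12 genes always (among them Hmgcs1, Insig1, Srebf2, Srebf1, Rhob, Fasn, Scd1, Abca1, Mitf and Mki67), the 8 largest changes each way among named protein-coding genes past an adjusted p of 0.05, up to 4 members past the threshold per list, or the 2 of highest expression where none passed. For the authors' tables the rule was the 5 terms of smallest adjusted p per database and the 5 network genes of highest degree, of which only some are named. The rule's expression minimum was written for FPKM. As the unit is not known, a mean value of at least 1 in the deposited unit was used, chosen after the values were seen. Some genes that the rule names, and 1 gene list, are not reported here. Chosen after the values were seen are also the 8 largest changes each way among most abundant transcripts, up to 4 further list members with the authors' call, the genes named from the aggressiveness and A375 tables, and genes named because they passed only when adjusted over the list alone or because they make up a small count.

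Gene totals were sums over a gene's transcripts. Correlations used 100000 permutations, overlaps Fisher's exact test, and both were two-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. A stricter adjusted p of 0.01 and an added absolute log2 fold change of at least 1 had been chosen in advance as other thresholds. Other settings were added after the data were seen: the authors' call, most abundant or Ensembl transcripts only, a gene total moving the same way by 1.2-fold, a mean value of at least 5 for counts and 1 for lists, a preset correlation of 0.05, ranks, the log2 fold change of the most abundant transcript as the statistic (without transcripts listed at 0 in a group), the log2 ratio of gene totals as the statistic, and every transcript as a row. Gene totals have no p-value, so that setting changed both the statistic and the unit tested. The comparison of the aggressiveness transcripts with the authors' other calls was also chosen after the data were seen.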

Results

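The study measured RNA in B16.F10 cells, a mouse melanoma line that makes pigment and colonises the lung, after 24 h with 3.5 µM simvastatin or with no treatment. Simvastatin is a statin, a drug that blocks the synthesis of mevalonate, which cells need for cholesterol and for the lipid anchors of small GTPases. Each group held 3 samples, which the series text calls biological replicates, and all 6 samples carry the same batch date. The tables used here give 1 value per group for each of 15905 transcripts of 8513 genes and no value per sample. No SD could therefore be computed, and the depth of each sample is unknown. The values of all transcripts summed to 344210 with simvastatin and 394749 in control, in a unit that is not given in the sources used here.

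The comparison of treated with untreated cells addressed how lipid metabolism genes and genes linked to drug resistance respond to the statin. Genes of cholesterol synthesis were higher with simvastatin, and genes of DNA replication and mitosis were lower. Genes of sterol uptake and sensing were higher as a list too, although that call depended on the statistic used. The list of mevalonate and cholesterol synthesis genes had a median log2 fold change of 1.02 over 21 measured genes, and the list of G2 and mitosis genes had a median of -0.90 over 30. Rhob, a small GTPase of endosomes and the actin cytoskeleton, rose 5.38-fold in the authors' deposited table, from 51.4 to 276 (adjusted p = 0.033). Klf2 and Klf4, zinc finger transcription factors, rose 30.9-fold and 25.3-fold from the low control values of 0.51 and 0.84 in the authors' deposited table (adjusted p = 0.038 and 0.042). The log2 fold changes per gene in the authors' deposited table of the human comparison were smaller, 3.47 and 3.60 (11.1-fold and 12.1-fold). Each of these genes has 1 transcript, so the gap does not come from summing transcripts. Adding 1 to each group value before taking the ratio gives these smaller folds, which shows how far the folds depend on the low control values.

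At an adjusted p under 0.05, the authors' deposited table held 176 higher and 157 lower transcripts, which belonged to 173 and 154 genes. The authors' own call, which reached an adjusted p of up to 0.2 and a fold of at least 1.5, covered 816 higher and 695 lower transcripts. Without adjustment 3120 transcripts (19.6%) had a p under 0.05 in the authors' deposited table, and at an adjusted p under 0.01 only 1 transcript remained, a transcript of the ubiquitin-conjugating enzyme gene Ube2h. Of 37 gene lists, 34 had at least 5 measured members, and limma's cameraPR placed 10 of these higher and 4 lower at an adjusted p under 0.05. The higher lists include mitochondrial transcripts and the lower ones histone and small nuclear RNA genes, both of which had been fixed as control lists. Over the 577 list genes measured, 21 were higher and 20 lower by the adjusted p over all transcripts, and 168 passed when adjusted over the list alone. No values per sample were used, so no inter-gene correlation could be estimated, and which list calls would hold with one is not known.

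**Figure D1:**
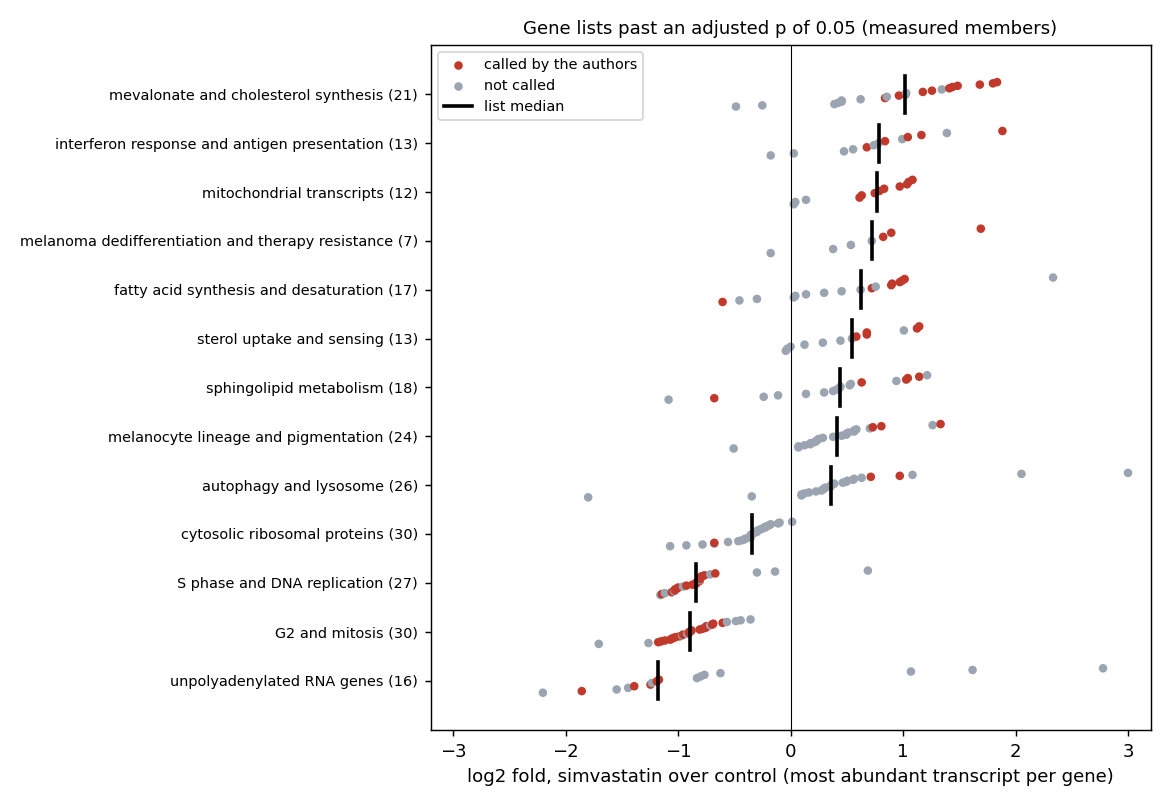
Log2 fold change with simvastatin over control (x axis) of the most abundant transcript of each measured gene in 13 of the 14 lists past an adjusted p of 0.05, with list sizes in brackets, medians as black bars and the authors' calls in red. The 30 G2 and mitosis genes all lie below 0, 19 of the 21 mevalonate and cholesterol synthesis genes lie above 0, and 1 gene beyond an absolute value of 3 is drawn at the edge.

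In the mevalonate and cholesterol synthesis list, 4 of 21 genes rose and none fell by the adjusted p over all transcripts, and 11 were higher and 1 lower when adjusted over the list alone (list adjusted p = 6.35e-07, limma's cameraPR). Hsd17b7, a late enzyme of cholesterol synthesis, rose 3.57-fold in the authors' deposited table (adjusted p = 0.044). An assembled transcript of Hmgcs1, which makes HMG-CoA (chromosome 13, 119690379 to 119708260 in GRCm38), rose 3.48-fold, and the sterol desaturase gene Sc5d rose 2.26-fold in the authors' deposited table (adjusted p = 0.041 and 0.042). Per gene, the human comparison in the authors' deposited table gave Hmgcs1 a smaller change, 1.56-fold. Idi1, the isopentenyl diphosphate isomerase, stood at 75.0 against 23.3, and Sqle, the squalene epoxidase, at 53.5 against 22.4 in the authors' deposited table (adjusted p = 0.072 and 0.122). The 1 gene on the lower side when adjusted over the list alone was Lbr, a sterol reductase of the inner nuclear membrane, named after its values were seen, with 24.8 against 29.4 in the authors' deposited table (adjusted p = 0.19).

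Of 13 measured genes of sterol uptake and sensing, 2 rose and none fell, and 6 were higher when adjusted over the list alone (median log2 fold change 0.55, list adjusted p = 0.00123). Insig2, which holds the SREBP complex in the endoplasmic reticulum, rose 1.60-fold in the authors' deposited table (adjusted p = 0.038). Insig1, its paralog, had values of 139 and 63.7 in the authors' deposited table (adjusted p = 0.056). The genes of the sterol-regulated transcription factors themselves did not pass: Srebf2 stood at 54.9 against 37.6 and Srebf1 at 6.70 against 10.2 in the authors' deposited table (adjusted p = 0.266 and 0.077). The call of this list ended when the log2 fold change replaced the p-based statistic (adjusted p = 0.206) and when the log2 ratio of gene totals, the sum over a gene's transcripts, replaced it (adjusted p = 0.146), with a median gene-total ratio of 0.45. The smallest adjusted p over the 7 settings tried was 0.000198.

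Fatty acid synthesis and desaturation genes were higher as a list of 17 (median log2 fold change 0.62, list adjusted p = 0.00388), with 2 members that rose, and 7 higher and 2 lower when adjusted over the list alone. Slc25a1, the mitochondrial citrate carrier, and Acss2, an acetyl-CoA synthetase, rose 1.96-fold and 1.87-fold in the authors' deposited table (adjusted p = 0.047 and 0.022). Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), stood at 179 against 90.0, and Scd1, a stearoyl-CoA desaturase, at 60.5 against 32.5 in the authors' deposited table (adjusted p = 0.055 and 0.083). The 2 genes on the lower side when adjusted over the list alone were Srebf1 and the acyl-CoA synthetase gene Acsl1. The sphingolipid list of 18 genes was also higher (median log2 fold change 0.44, list adjusted p = 0.00376), with 1 gene that rose by the printed adjusted p and 4 higher when adjusted over the list alone, the others being Smpd1, Sptlc2 and the glucosylceramide synthase gene Ugcg. Ugcg is printed at 0.05, and its adjusted p with more digits was 0.0499 in the human comparison of the authors' deposited table. The gene that rose, Kdsr, which reduces ketosphinganine to sphinganine, rose 2.21-fold in the authors' deposited table (adjusted p = 0.038). The calls of both lists ended with log2 fold changes as the statistic (adjusted p = 0.159 for fatty acids and 0.274 for sphingolipids) and with log2 ratios of gene totals (0.147 and 0.158). Their median gene-total ratios were 0.53 and 0.46, and the smallest adjusted p over the 7 settings was 0.00284 and 0.000296.

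Other lipid lists did not pass. Genes of lipid uptake, droplets and lipolysis (10 measured, median 0.32, list adjusted p = 0.069) had 1 gene that rose, the fatty acid transporter gene Slc27a4, by 1.66-fold in the authors' deposited table (adjusted p = 0.019), and 5 higher and 1 lower, the fatty acid binding protein gene Fabp5, when adjusted over the list alone. The other higher genes were those of the lipases Pnpla2 and Mgll, the lipase activator Abhd5 and the droplet protein Plin3. Mgll, a monoacylglycerol lipase, stood at 38.8 against 4.22 in the authors' deposited table (adjusted p = 0.062). Sterol efflux and LXR target genes (8 measured, list adjusted p = 0.688 by limma's cameraPR) had 2 higher members (Smpdl3a and the cholesteryl ester hydrolase gene Nceh1) and 2 lower (Abca1 and the cholesterol acyltransferase gene Soat1) when adjusted over the list alone. Smpdl3a, a phosphodiesterase, rose 1.77-fold, while Abca1, which exports cholesterol, had values of 1.09 and 3.40 in the authors' deposited table (adjusted p = 0.049 and 0.079). On most abundant transcripts, no member passed over all transcripts among 14 glycerolipid and phospholipid synthesis genes (list adjusted p = 0.394), 22 fatty acid oxidation genes (0.394) and 5 prostaglandin and eicosanoid genes (0.689, limma's cameraPR). In the last of these lists 1 gene was higher past the threshold on a less abundant transcript. When adjusted over the list alone, these lists held 1, 0 and 1 higher genes, namely Pcyt2, of phosphatidylethanolamine synthesis, and Ptgds. The prostaglandin list was higher with every transcript as a row (adjusted p = 0.00633, and up to 0.898 in the other settings). Ptgds, the prostaglandin D synthase, had the values 350 and 90.3 in the authors' deposited table (adjusted p = 0.071).

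Of single genes of small GTPases, many of which carry prenyl anchors made from mevalonate, Rhob (chromosome 12, 8497661 to 8500009) and Rala, a regulator of exocytosis, rose 5.38-fold and 1.42-fold in the authors' deposited table (adjusted p = 0.033 and 0.038). Rhoa, which drives actin contractility, had values of 192 and 124 in the authors' deposited table (adjusted p = 0.056). Among the 11 genes of protein prenylation none passed on either adjustment (list adjusted p = 0.301). The 15 YAP and TEAD target genes had 1 higher, the transcription factor gene Tead4, and 3 lower, Cyr61, Ajuba and F3, when adjusted over the list alone (list adjusted p = 0.394). The list of 17 SRF and MRTF targets, which encode actin and its partners, did not pass (adjusted p = 0.121). In it, Cnn2, a calponin, and Actg1, a cytoplasmic actin, fell 2.31-fold and 2.20-fold in the authors' deposited table (adjusted p = 0.042 and 0.038). When adjusted over the list alone 4 were lower, with Vcl, for vinculin, and Tpm1, for a tropomyosin, beside these. With every transcript as a row the SRF and MRTF list was lower (adjusted p = 0.0198, and up to 0.645 in the other settings).

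Proliferation genes were lower. In the S phase and DNA replication list 7 of 27 genes fell, and 20 were lower when adjusted over the list alone (median log2 fold change -0.84, list adjusted p = 1.93e-12). Cdt1, which licenses replication origins, Mcm3 and Mcm2 of the replicative helicase, and Rrm2, a ribonucleotide reductase subunit, fell 2.21-fold, 2.08-fold, 1.83-fold and 2.01-fold in the authors' deposited table (adjusted p from 0.033 to 0.045). In the G2 and mitosis list 8 of 30 genes fell, and 23 were lower when adjusted over the list alone (list adjusted p = 1.59e-14). Cdc20, an activator of the anaphase-promoting complex, the cyclin gene Ccnb2, the kinase gene Aurkb and the cyclin-dependent kinase gene Cdk1 fell 2.22-fold, 2.17-fold, 2.08-fold and 1.98-fold in the authors' deposited table (adjusted p from 0.038 to 0.049). Mki67, a common proliferation marker, had values of 7.90 and 10.8 for its most abundant transcript in the authors' deposited table (adjusted p = 0.94). The 16 p53 targets and CDK inhibitors did not pass as a list (adjusted p = 0.484), with the CDK inhibitor gene Cdkn1b the 1 gene higher when adjusted over the list alone. Cdkn1a, the p53-induced inhibitor, had values of 103 and 102 in the authors' deposited table (adjusted p = 0.838). Among 18 apoptosis regulators no gene passed over all transcripts, and 2 were higher (Bmf and Cflar) and 2 lower (Cycs, for cytochrome c, and Fadd) when adjusted over the list alone (list adjusted p = 0.898).

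Histone genes and ribosomal protein transcripts were lower beside these lists. The control list of histone and small nuclear RNA genes had a median log2 fold change of -1.18 over 16 measured genes (list adjusted p = 0.0118). On most abundant transcripts no gene passed over all transcripts, and 4 were lower when adjusted over the list alone (Hist1h2ab, Hist1h2ae, Hist1h4d and Hist2h2ac). In this list 1 gene was lower past the threshold on a less abundant transcript. The list's call ended with a preset correlation of 0.05 and with Ensembl transcripts only (adjusted p = 0.0613 and 0.0512, with 1.36e-05 the smallest over the 7 settings). Hist1h2ab, a core histone gene of the large cluster on chromosome 13, had values of 185 and 486 in the authors' deposited table (adjusted p = 0.052). Cytosolic ribosomal protein genes had a median of -0.34 over 30 genes (list adjusted p = 6.54e-06). Rps15 and Rpl32 fell 1.38-fold and 1.19-fold in the authors' deposited table (adjusted p = 0.042 and 0.038). Adjusted over the list alone, 7 ribosomal protein genes were lower. The list did not pass with log2 fold changes as the statistic (adjusted p = 0.152) or with log2 ratios of gene totals (adjusted p = 0.121), whose median was -0.37, and 2.11e-06 was the smallest adjusted p over the 7 settings.

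Lists of cell state were higher. Of 24 melanocyte lineage and pigmentation genes 1 rose by the printed adjusted p, Gpnmb, a melanosome glycoprotein gene, by 1.75-fold to 1856 in the authors' deposited table (adjusted p = 0.042). Gpr143, a melanosome receptor gene, is printed at an adjusted p of 0.05 with 1.66-fold, and at 0.0496 with more digits in the human comparison of the authors' deposited table. Of the 24, 7 were higher when adjusted over the list alone (median log2 fold change 0.42, list adjusted p = 0.000833). Mitf, the lineage transcription factor, had values of 133 and 122 in the authors' deposited table (adjusted p = 0.714). In the list of melanoma dedifferentiation and therapy resistance genes, 7 of 30 were measured and were higher as a list (median 0.72, adjusted p = 0.0294, limma's cameraPR). Sox9, a neural crest transcription factor, rose 3.23-fold in the authors' deposited table (adjusted p = 0.043), and 3, with Jun and Tead4, were higher when adjusted over the list alone. Both calls ended with log2 fold changes as the statistic (adjusted p = 0.193 and 0.197) and with log2 ratios of gene totals (adjusted p = 0.121 and 0.163), whose medians were 0.27 and 0.54. The call of the dedifferentiation list also ended with every transcript as a row, with Ensembl transcripts only and with a preset correlation of 0.05 (adjusted p = 0.123, 0.0726 and 0.0613). The smallest adjusted p over the 7 settings was 2.54e-05 for melanocyte genes and 0.0303 for dedifferentiation genes. Interferon response and antigen presentation genes were higher over 13 measured genes (median 0.78, list adjusted p = 0.00136). Irf9, which binds DNA in the interferon-activated complex, rose 3.69-fold in the authors' deposited table (adjusted p = 0.047), and 5 were higher when adjusted over the list alone (Irf9, Irf1, Rsad2, Ifi35 and Tapbp). In the list of epithelial to mesenchymal transition and matrix genes, which did not pass (20 measured, adjusted p = 0.394), the integrin genes Itgb3 and Itgb1 rose 7.18-fold and 1.19-fold in the authors' deposited table (adjusted p = 0.038 and 0.042), and 3 genes, with Cd44, were higher when adjusted over the list alone.

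Autophagy and lysosome genes were higher as a list of 26 with no single gene past the threshold (median log2 fold change 0.36, list adjusted p = 0.0073). The lysosomal proteases Ctsd and Ctsb had values of 646 and 217 with simvastatin against 441 and 111 in control in the authors' deposited table (adjusted p = 0.306 and 0.053). Ctsb was the 1 gene higher when adjusted over the list alone. The call ended with log2 fold changes as the statistic, with log2 ratios of gene totals and with a preset correlation of 0.05 (adjusted p = 0.23, 0.146 and 0.0613, with 0.00162 the smallest over the 7 settings), while the median gene-total ratio was 0.36. Of 13 protein-coding genes of the mitochondrial genome 12 were measured, all but mt-Co3, and all 12 were above 0 (median 0.77, list adjusted p = 9.07e-05), with none past the threshold over all transcripts and 9 higher when adjusted over the list alone. The call ended with log2 fold changes as the statistic (adjusted p = 0.118, with 2.23e-06 the smallest over the 7 settings). For mt-Co1, a subunit of cytochrome c oxidase, the authors' deposited table gave 2138 and 1034 (adjusted p = 0.063). The 29 nuclear genes of the respiratory chain had a median of -0.16 and did not pass as a list (adjusted p = 0.0638), although they were lower on ranks of the statistic (adjusted p = 0.0169, and up to 0.857 in the other settings).

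Among the stress lists, 27 NRF2 and antioxidant genes did not pass (list adjusted p = 0.159). Among them, Srxn1, a sulfiredoxin, and G6pdx, of the pentose phosphate pathway, rose 2.03-fold and 1.5-fold in the authors' deposited table (adjusted p = 0.044 and 0.038), and 6 were higher when adjusted over the list alone. The 12 heat shock and handling stress genes did not pass either (list adjusted p = 0.127). The chaperonin gene Hspd1 fell 1.62-fold in the authors' deposited table (adjusted p = 0.043), with 2 higher, the stress-induced transcription factor genes Jun and Atf3, and 6 lower when adjusted over the list alone. With every transcript as a row that list was lower (adjusted p = 0.00724, and up to 0.933 in the other settings). The 28 genes of the integrated stress and unfolded protein response had 5 higher (Atf3, Slc7a11, Edem1, Ern1 and Atf6) and 4 lower (Atf5, Phgdh, Hspa5 and Creld2) when adjusted over the list alone and did not pass as a list (adjusted p = 0.862). The remaining lists had no gene past the threshold over all transcripts. They covered ferroptosis regulators (list adjusted p = 0.394), drug efflux transporters (0.301, limma's cameraPR), NF-kappaB and cytokine genes (0.369), glycolysis (0.495), and angiogenesis and hypoxia (0.977). Adjusted over the list alone, 1 drug efflux gene, Abcc5, and 1 hypoxia gene, Ndrg1, were higher and none of the others passed. The median log2 fold change of the glycolysis list was -0.01 while its test pointed up. Markers of other cell types were nearly absent from the table, with 0 of 11 fibroblast and stromal genes, 0 of 11 keratinocyte and endothelial genes and 1 of 14 macrophage and leukocyte genes measured. That gene, Cd68, a lysosomal protein of macrophages, had values of 0.93 and 0.37 in the authors' deposited table (adjusted p = 0.977).

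The largest folds mostly fell on single transcripts of genes with several. Among transcripts past the threshold, those of Sh3kbp1, an endocytic adaptor, and Npm1, a nucleolar chaperone, had 2.74 and 47.2 with simvastatin and were listed at 0 in control in the authors' deposited table (adjusted p = 0.018 and 0.022). The other 6 largest increases were in Ube2h, in Lgals4, a galectin, in the endocytic adaptor gene Epn2, in Paip2, a repressor of translation, in Fam208a, a silencing factor, and in Klf2. Their values in the authors' deposited table were 40.7 against 0.05 for Ube2h, 9.61 against 0.04 for Lgals4, 2.73 against 0.01 for Epn2, 4.44 against 0.12 for Paip2 and 5.88 against 0.17 for Fam208a. In the other direction, transcripts of Dgkz, a diacylglycerol kinase, and of the nuclear pore gene Nup93 were listed at 0 with simvastatin and had 3.11 and 14.8 in control in the authors' deposited table (adjusted p = 0.043 and 0.042). The next were Syne2, a linker of nucleus and cytoskeleton (0.02 against 14.04), Cnst, linked to connexin trafficking (0.01 against 4.60), Trim46, of the axon initial segment (0.01 against 6.76), Nol9, a nucleolar kinase (0.02 against 7.61), Eef1akmt1, a lysine methyltransferase (0.03 against 9.78), and the chaperone gene Hsp90aa1 (0.76 against 249) in the authors' deposited table. Gene totals went the other way for 6 of these 16 genes: Npm1, Epn2, Paip2, Syne2, Cnst and Eef1akmt1. For Npm1 the total over its 3 transcripts in the authors' deposited table was 207 with simvastatin and 253 in control.

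Of the 1511 transcripts called by the authors, 812 belonged to genes with several transcripts, and the gene total went the other way for 114 of these and moved by less than 1.2-fold for 161. In 47 genes the authors' deposited table called transcripts in both directions. Among most abundant transcripts alone, 150 were higher and 118 lower at an adjusted p under 0.05. After Sh3kbp1, Lgals4, Fam208a, Klf2 and Klf4, the next increases by size among named protein-coding genes there were in Fam49a, a regulator of actin protrusions (23.1-fold), and in the membrane protein genes Tmem150a (11.7-fold) and Tmem151a (9.47-fold) in the authors' deposited table (adjusted p = 0.043, 0.038 and 0.037). The 8 largest decreases there included, beside Trim46, the metalloprotease gene Adam12 (6.41-fold) and the mRNA-binding protein gene Igf2bp1 (3.23-fold) in the authors' deposited table (adjusted p = 0.018 and 0.042). The linker histone gene Hist1h1a had 0.20 against 3.77 and the translesion polymerase gene Poli 0.03 against 2.75 in the authors' deposited table (adjusted p = 0.043 and 0.033).

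**Figure D2:**
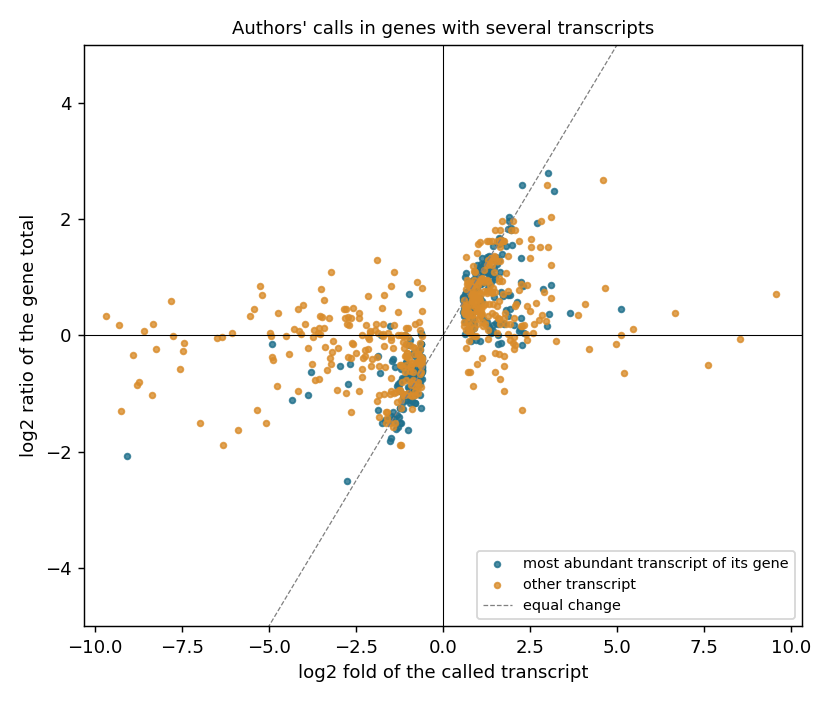
Log2 fold of each transcript called by the authors (x axis) against the log2 ratio of its gene's total over all transcripts (y axis), for 803 of the 812 calls in genes with several transcripts; the 9 others had a group listed at 0. Points on the dashed line would mark a gene total that moved as far as the transcript, and 161 of the 812 calls have a gene total within 1.2-fold.

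The authors' enrichment terms followed the same groups. The terms come from the same samples as the list tests, so this is not independent evidence. The authors' deposited table held 80 terms for higher and 68 for lower genes. Among biological processes for higher genes, the authors' deposited table led with lipid metabolic process (67 genes, 3.49-fold, adjusted p = 6.68e-15), sterol biosynthetic process (15 genes, 18.7-fold, adjusted p = 1.63e-11) and cholesterol biosynthetic process (16 genes, 14.7-fold, adjusted p = 8.12e-11). The KEGG terms of smallest adjusted p for higher genes were metabolic pathways, lysosome, steroid biosynthesis, chemical carcinogenesis by reactive oxygen species, and Alzheimer disease, from 4.94e-05 to 0.00161 in the authors' deposited table. Of the 30 KEGG terms for higher genes, 11 contained mitochondrially encoded genes, with 9 such genes among the 35 of the Alzheimer disease term. For lower genes the processes of smallest adjusted p were cell cycle (95 genes, 8.0-fold, adjusted p = 6.46e-53) and cell division (71 genes, 9.52-fold, adjusted p = 7.66e-44) in the authors' deposited table. The KEGG terms for systemic lupus erythematosus and alcoholism, 41 and 42 genes, each held 39 histone genes in the authors' deposited table. Over all 148 terms a median of 94.2% of the identifiers listed carried the authors' call in the term's direction. These shares cover only the identifiers listed, and 16 terms listed fewer than their count, such as 21 of 353 for nucleus among lower genes in the authors' deposited table. Identifiers with the call made up under 50% of those listed in 5 terms, intracellular signal transduction (10 of 44), transport (9 of 38), transmembrane transport (1 of 37), positive regulation of nervous system development (1 of 13) and immune response for lower genes (4 of 33). In that order, only 21, 13, 3, 1 and 10 of the listed identifiers were among the genes measured here. Most of those without the call were therefore not measured.

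The authors' protein network joined 46 genes, 9 of them encoded in the mitochondrial genome, by 167 links of a score over 0.7 in their deposited table, and 43 of these genes carried a higher call on at least 1 transcript and 0 a lower one, while Mvk, Pmvk and Cox7a2 had no call. For 6 of the 43 (Lss, Acat2, Tm7sf2, Pgls, Pld1 and Cox6b1) the call was on a transcript other than the most abundant, which lay below 0 for the last 4. The genes of highest degree in the authors' deposited table were Lss, the lanosterol synthase, with 14, and Fasn, Fdps, Mvd and Sqle with 13 each, of which Fdps makes farnesyl diphosphate and Mvd decarboxylates mevalonate diphosphate. For 10 of the 46 genes the degree in the authors' deposited table differed from the links counted there, which were 11 for Fasn and for Sqle. The genes were chosen by the authors from these samples, so their direction is not independent evidence.

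A further table of the authors listed 46 transcripts as linked to tumour aggressiveness, 43 higher and 3 lower. Of these, 11 (23.9%) had an adjusted p under 0.05, 10 higher and 1 lower, and none had one under 0.01. All 46 carried the authors' call, and of the 1465 other transcripts with that call 248 (16.9%) had an adjusted p under 0.05 (odds ratio 1.54, Fisher's exact p = 0.232, two-sided). Past the threshold were, among others, Fam49a, Itgb3, Rhob and Erbb3, a receptor tyrosine kinase gene with 44.5 against 13.2 in the authors' deposited table (adjusted p = 0.038). On the lower side was Bcl2l13, a mitochondrial member of the BCL2 family, with 0.37 against 3.27 in the authors' deposited table (adjusted p = 0.038). For 7 of the 46 the gene total moved by less than 1.2-fold, Bcl2l13 among them, and for 4 (Sp3, Cd81, Atf5 and Ect2) it went the other way.

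The authors also set 158 genes, chosen by a transcript's adjusted p under 0.05, beside the human melanoma line A375 treated with 10 µM simvastatin, taken from an outside signature. As printed, 325 genes had a transcript past that threshold. Why the others were left out is not known here, so what follows covers only these 158 genes. Across these genes the mouse log2 fold change correlated with the A375 z-score, with a Pearson r of 0.496 and a Spearman correlation of 0.546 (permutation p = 1e-05 for each, the smallest possible, and adjusted p = 1e-05 over the 6 relations computed). The correlation is across genes, which are not independent replicates, and the doses differed. The mouse value is per gene, and for 11 of the 156 entries whose adjusted p matched a transcript it lay on the other side of 0 from that transcript, as for Epn2 and the transcription factor gene Sp3 with -0.25 and -0.32 in the authors' deposited table. Both were higher for 72 genes and both lower for 46, so that 74.7% had the same sign (odds ratio 8.36, Fisher's exact p = 1.73e-09, two-sided). Any z-score above or below 0 was counted here, however small, and 44 of the 158 genes had an absolute z-score of at least 2. All 11 of the 158 genes in the S phase or G2 and mitosis lists were lower in both, with a median z-score of -3.83. The topoisomerase gene Top2a had the z-score of -9.22 in the authors' deposited table. Cdt1 and Aurkb, which also fell in the mouse cells, were not among the 158. Of 5 genes of the sterol and fatty acid lists, 3 were higher in both, among them Hsd17b7 with a z-score of 0.818 and Hmgcs1 with 0.573 in the authors' deposited table. Slc25a1 had a z-score of -0.359 in the authors' deposited table. Rhob and Klf2 had z-scores of 1.73 and 1.79 in the authors' deposited table.

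**Figure D3:**
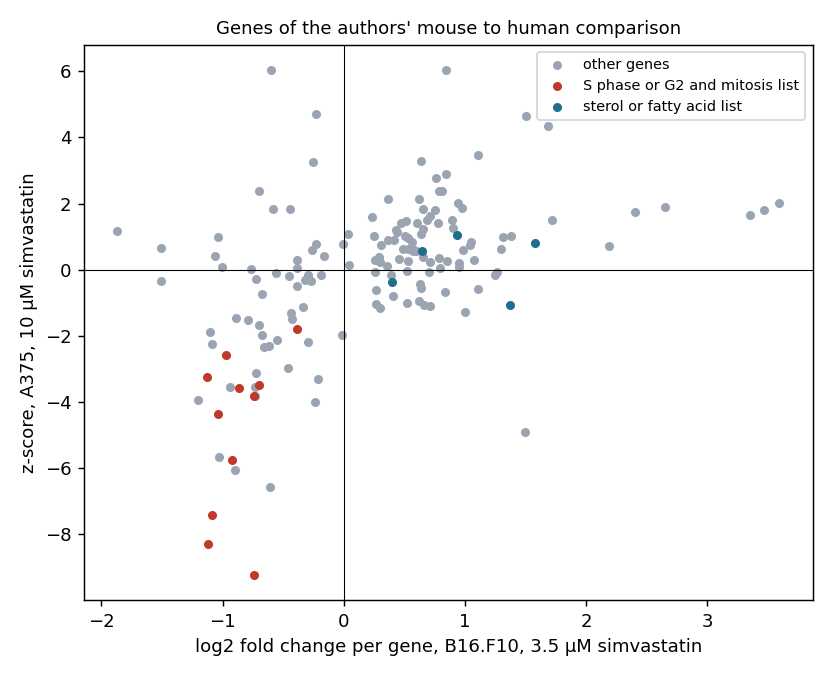
Log2 fold change per gene in B16.F10 cells with 3.5 µM simvastatin (x axis) against the z-score in A375 cells with 10 µM simvastatin (y axis) for the 158 genes of the authors' comparison, 1 point per gene. The 11 of these genes in the S phase or G2 and mitosis lists (red) all lie below 0 on both axes, and 118 genes have the same sign on both.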

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

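The thresholds of 0.01 and of an absolute log2 fold change of 1 were chosen in advance, and the other settings after the data were seen. At an adjusted p under 0.01, 1 transcript was higher and 0 were lower, and 0% of the aggressiveness transcripts passed. With an absolute log2 fold change of at least 1 added, 74 were higher and 71 lower. By the authors' own call 816 were higher and 695 lower. The 4 other settings for these counts gave 146 to 154 higher and 118 to 130 lower transcripts, against 176 and 157. The list members past the threshold numbered 143 by the authors' call and 168 when adjusted over the list alone, against 41. With the log2 fold change in place of the p-based statistic 5 lists passed, and with the log2 ratio of gene totals, which changes the statistic and the unit together, 6 passed, against 14. The 5 other list settings gave 10 to 16. In every one of the 7 list settings 4 lists passed: G2 and mitosis, S phase, mevalonate and cholesterol synthesis, and interferon response (largest adjusted p 0.0454). None of the 14 lists changed direction. Of lists that did not pass, hypoxia, apoptosis, glycolysis and the stress response changed direction in at least 1 setting. For 6 of 72 transcripts chosen by the naming rules in genes with several transcripts the gene total went the other way, with log2 ratios of -0.29 for Npm1, -0.50 for Epn2, -0.64 for Paip2, 0.33 for Syne2, 0.18 for Cnst and 0.072 for Eef1akmt1. It also did so for 4 transcripts of the aggressiveness table, with -0.10 for Sp3, -0.08 for Cd81, -0.53 for Atf5 and -0.87 for Ect2. Beyond the stricter thresholds, which by construction leave fewer transcripts, the cause was not tested. The A375 correlation across genes was 0.521 without 5 entries that repeated a z-score or identifier or whose identifier did not match, and 0.415 without the S phase and the G2 and mitosis lists, against 0.496. These lists do not hold every proliferation gene, and Kif14 and Melk, with z-scores of -6.56 and -5.67, remained. The value of 0.415 is therefore not a correlation apart from the cell cycle.

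No paired analysis was possible because the tables used here give 1 value per group and none per sample. For the same reason another test, another normalization, another filter on low values, other pseudocounts, leaving out each replicate, an estimated inter-gene correlation and fry were not run, and other splits of the samples could not be counted. Sequencing depth is unknown, so what it limits could not be told.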

Other observations

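The tests of symbol stems and of explanations in this part were chosen only after the results were seen. All genes, members of the fixed lists included, were grouped by the letters before the first digit of their symbol, so some stems repeat list results. For these groups limma's cameraPR tested the 128 stems with at least 8 genes, of which 5 were higher and 11 lower at an adjusted p under 0.05. The Krüppel-like factor genes (Klf), zinc finger transcription factors, were higher over 9 genes, with a median log2 fold change of 1.32 (adjusted p = 0.00957). Klf2, Klf4 and Klf6 rose, the last by 3.08-fold in the authors' deposited table (adjusted p = 0.025), while Klf10 had values of 3.39 and 5.53 in the authors' deposited table (adjusted p = 0.106). Genes named Gpr, a group by name only, were higher over 10 genes (median 0.73, adjusted p = 0.000273). Among them, Gpr137b, a lysosomal membrane protein, rose 2.82-fold in the authors' deposited table (adjusted p = 0.04). Solute carriers (Slc, 126 genes, median 0.24), vacuolar sorting genes (Vps, 27 genes, median 0.38) and secretory pathway genes (Sec, 22 genes, median 0.33) were also higher (adjusted p = 0.0248, 0.0406 and 0.0406). Among the lower stems were genes of mitochondrial ribosomes (Mrpl, 46 genes, median -0.39), nuclear pores (Nup, 19 genes, median -0.34) and RNA splicing (Srsf, 10 genes, median -0.54), with adjusted p of 0.000208, 0.014 and 0.0292. No Vps, Mrpl or Srsf gene passed the threshold on its most abundant transcript, and no Vps or Srsf gene carried the authors' call there. Other settings were not tried for the stems.

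The small RNAs Rn7sk, Rn7s1, Rn7s2, Rmrp and Rpph1 made up 10.7% of the sum of all values with simvastatin and 14.6% in control. They were chosen after the values were seen, and none passed the threshold (adjusted p from 0.303 to 0.744 in the authors' deposited table).

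Large folds on single transcripts were the first pattern weighed. In genes with several transcripts, 42 transcripts of 40 genes passed the threshold with at least 4-fold change, and their median absolute log2 fold was 3.86. The median absolute log2 ratio of their gene totals was 0.35, which argues against a change of the whole gene's output as the source of folds of that size. Assembled models made up 47.6% of them and 31.4% of the other transcripts of such genes (odds ratio 1.99, Fisher's exact p = 0.0298), so assignment of reads to models assembled from the same data may contribute. A switch between transcripts with simvastatin stays open as the biological explanation, since 1 value per group cannot show whether samples move together.

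The second pattern was the histone cluster genes (stem Hist), with a median log2 fold change of -1.32 over 62 genes, 59 of them below 0 and 12 past the threshold. A lower yield of RNA without a poly(A) tail would lower all such RNA alike. The histone genes lay below 82 other genes of small nuclear, nucleolar and related RNAs, whose median was -0.56, by a difference of -0.77 (permutation p = 1e-05, the smallest possible, two-sided), which argues against that yield as the whole cause. The permutation is over genes, which are not independent replicates, so its p does not measure spread between cultures. Fewer cells in S phase may account for part, as the polyadenylated S phase genes had a median of -0.84. A smaller loss of such RNA stays open, since 65 of the 82 lay below 0, although none passed an adjusted p of 0.05 and 12 had an unadjusted p under 0.05.

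The third pattern was the rise in value of the 12 measured mitochondrially encoded protein genes, with a median log2 fold change of 0.77. A scaling effect on all transcripts would need a like shift elsewhere. In the deposited values, whose normalization is not given, the median over all transcripts was 0.014 (95% bootstrap interval 0 to 0.0286), so they held no such shared shift. The interval is over transcripts and does not measure spread between cultures. A shift shared with the 29 nuclear respiratory chain genes is argued against by a difference of medians of 0.93 (permutation p = 9e-05, two-sided). That permutation is over genes, which are not independent replicates, so its p does not measure spread between cultures. More mitochondrial relative to cytoplasmic RNA in the treated samples might explain it, but ribosomal and transfer RNA genes of mitochondria had a median of 0.50 with 11 of 17 above 0 (exact sign test p = 0.332, two-sided), which leaves this open. A response of mitochondrial transcription to simvastatin was not tested.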
